A study of Homo sapiens with 16 samples.

How the data were processed

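RNA of K1106 cells was measured in 3 arms: cells given the JAK2 inhibitor TG101348 (8 arrays), cells with an induced JAK2 shRNA (4 arrays) and cells with an induced JMJD2C shRNA (4 arrays). The authors' scanner files hold the spot signals of both channels as intensity, per the file headers from Agilent Feature Extraction 10.1.1.1 for the inhibitor arrays and 9.5.3.1 for the shRNA arrays, while the labels give 9.1.3.1 throughout. The deposited series values are the log10 ratio of the Cy5 over the Cy3 processed signal, within 0.0005 of the values recomputed from the scanner files, with no further centring. The scanner files' own log ratio was not used in the main fits, because 15.8% to 22.7% of its entries were exactly 0. It served only in an alternative, named below by the scanner software's processed signals or values.

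From the scanner files, the mean signal of each spot was corrected for its local background median with normexp (offset 50) and normalised within each array by loess, with control spots at weight 0. Spots marked as non-uniform outliers, 0 to 96 per array, were left out. Spots of a probe were averaged and 1 probe per gene was kept, the one with the highest mean intensity. Probes were given gene names from the RefSeq accession in the file (25876 spots), the symbol (2937) or a synonym (1137), and 13426 spots kept the name in the file. Of 30499 gene names 7782 had several probes. A gene was tested if it was well above background in either channel on at least a 0.5 share of the arrays in its fit, and 14 to 184 genes per fit with a missing spot were left out. Median channel intensities were 153.7 to 182.7 (Cy3) and 184.9 to 220.3 (Cy5) in the inhibitor arm, 75.7 to 88.1 and 120.4 to 129.3 in the JAK2 shRNA arm, and 105.3 to 108 and 154.9 to 193.4 in the JMJD2C shRNA arm. The number of arrays limits the precision.

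Linear models were fitted with limma 3.58.1 (R 4.3.3, statmod 1.5.0, with the data.table package at 1.17.8), with moderated statistics and Benjamini-Hochberg adjusted p. A gene was called at adjusted p below 0.05 and a log2 size of at least 0.5. The fits gave the mean change of the inhibitor arm, its trend on log2 hours (reported as the fitted change from 0.5 to 48 h), the mean change of each shRNA arm in a shared fit, the difference of those means, the trend of each shRNA arm (24 to 96 h), and the inhibitor minus the JAK2 shRNA at 24 and 48 h. Genes called alike were those called in both shRNA arms in 1 direction. The number that independent calls would share was the product of the called shares times the genes tested. Genes were named by a rule: the 10 largest called changes in each direction, JAK2 and JMJD2C, and examples from the lists. The rule of 10 was not applied to the shRNA trends or to the inhibitor minus the JAK2 shRNA. Genes named there are the targets and examples from the lists. For an arm mean, only genes with the same sign on every array were eligible for the 10. For the difference of the shRNA arms, only genes whose arms did not overlap were eligible. Accessions and open reading frame names were left out, and statements of the largest rise or fall hold among the eligible genes. The 26 gene lists (477 genes, 34 of them in several lists) came from general knowledge of pathways: JAK-STAT targets, STAT6 targets, PMBL signature, 9p24 amplicon, MYC and ribosome biogenesis, cell cycle, interferon response, NF-kB targets, H3K9 and heterochromatin machinery, BCL2 family, p53 targets, B cell identity, plasma cell genes, MHC class II, cholesterol synthesis, ATF4 stress response, ER chaperones, heat shock proteins, hypoxia and glycolysis, oxidative phosphorylation, mitochondrial ribosome, cytosolic ribosomal proteins, immediate early genes, replication-dependent histones, T cell markers, and monocyte and granulocyte markers. Each list with at least 5 measured genes was tested with camera at a preset correlation of 0.01, with camera at an estimated correlation and with fry, and p was adjusted over the lists of a comparison. The comparisons, the rule for named genes, the lists and the alternatives below, except where stated, were chosen before the data were examined.

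The alternatives were no background correction, the scanner software's processed signals, median centring in place of loess, the deposited series values, no filter and a stricter filter on dim probes, the mean of all probes of a gene, no size minimum and a minimum of 1, array weights, 1 fit of all 16 arrays, each shRNA arm alone, each shRNA array left out in turn, time as a block, an arm slope, several subsets of the inhibitor times, later arrays minus the 0.5 h array, the rank of time, slide as a block, a partial correlation given the 0.5 h array, and only the 4 arrays at the shared times. Leaving out each inhibitor array, each array of the inhibitor minus JAK2 shRNA comparison, and each array for the list tests was added after the data were seen. The models were tested on simulated data with 100 shifted genes per size. Of genes shifted by 0.75, 99% were recovered in the inhibitor mean, 39% in its trend, 93% and 96% in the JAK2 and JMJD2C shRNA means, 89% in their difference, 37% and 40% in the shRNA trends and 51% in the inhibitor minus the JAK2 shRNA. Of genes shifted by 1.5, 84% to 100% were recovered, and 1 to 10 unchanged genes were called per comparison. The shifted list was called in 8 of 8 comparisons and the other lists in 0 of 200 tests. The simulated noise was independent between genes, while estimated correlations within the real lists reached 0.5765 in the inhibitor mean. The simulation therefore does not show how often lists of correlated genes are called falsely. Its noise was also independent between arrays and centred on 0, with no dye bias and no slide effect. The 1 to 10 calls of unchanged genes are thus no estimate of the false calls among the real arrays. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15. Probe positions were taken from the hg18 NCBI36 coordinates in the inhibitor arrays' files, since the shRNA arrays' files use hg17 NCBI35.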

Results

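Gene expression was measured in K1106 cells, a line established from primary mediastinal B-cell lymphoma (PMBL), on 16 dual-colour Agilent arrays. In the first arm, 8 arrays compared cells given 2 uM TG101348, an inhibitor of the kinase JAK2, with cells given its solvent DMSO at 0.5, 2, 4, 6, 8, 16, 24 and 48 h. In the second arm, 4 arrays compared cells in which doxycycline (20 ug/ml) induced an shRNA against JAK2 with uninduced cells at 24, 48, 72 and 96 h. The third arm used an shRNA against JMJD2C (KDM4C, a demethylase of histone H3 at lysine K9) at the same 4 times. JAK2 and JMJD2C lie close together on chromosome 9, in the 9p24 segment that is often gained in this lymphoma. The comparisons ask what each treatment changed, and which changes the 2 shRNAs shared.

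Each time point had 1 array, so the time points of an arm stood in as its replicates, and nothing in the labels says whether they were separate cultures or whether controls were 1 shared pool. The p-values thus measure the spread between these arrays, part of which may be technical. The treated RNA was labelled with Cy5 and the control RNA with Cy3 on every array. There was no array with the dyes exchanged, so a gene's dye bias cannot be told apart from its mean change, though a bias equal on all arrays cancels in differences and time trends. No arm received doxycycline alone. Of 43376 spots that were not controls, 22117 to 27322 per array were well above background in Cy3 and 25198 to 29242 in Cy5. Across 20430 genes, which are not independent replicates, the log2 ratios of pairs of arrays correlated at r = 0.145 to 0.866 within the inhibitor arm (median 0.590), 0.832 to 0.974 within the JAK2 shRNA arm and 0.643 to 0.871 within the JMJD2C shRNA arm. Sizes are log2 ratios of treated over control, after a loess fit that brings the bulk of genes on each array to 0 along the range of intensity. With median centring in its place, the median of all tested genes lay at 0.43 in the JAK2 shRNA arm, 0.25 in the JMJD2C shRNA arm, 0.17 in their difference, 0.09 in the inhibitor arm, −0.12 in its time trend and −0.17 in the inhibitor minus the JAK2 shRNA. Changes are therefore relative to the bulk of genes of similar intensity. Turns of direction with median centring are given for lists and for genes named here, not for every called gene. In the JAK2 shRNA arm 1936 genes were called lower with loess and 447 with median centring.

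At its brightest probe, each targeted mRNA was lower in its shRNA arm than in uninduced cells, relative to the bulk of genes. The other arm and the second JMJD2C probe, given below, leave open whether the falls were specific to the target. JAK2 fell by 0.70 ± 0.12 (SD, n = 4 arrays; adjusted p = 7.50e-06) in the JAK2 shRNA arm, to 0.617 of the uninduced level, and was lower on 4 of 4 arrays. JMJD2C fell by 0.50 ± 0.14 (SD, n = 4 arrays; adjusted p = 0.000376) in the JMJD2C shRNA arm, to 0.706 of the uninduced level, and was also lower on 4 of 4. The fall in JMJD2C sat at the 0.5 limit for a call: it was −0.45 without the 48 h array and −0.48 without the 96 h array, which missed it. With median centring JAK2 stood at 0.07 and JMJD2C at 0.05, which were −0.36 and −0.20 relative to the median of all genes. The JAK2 probe lies on chromosome 9 at 5116773 to 5116832 and the JMJD2C probe at 7165334 to 7165393 (build hg18 NCBI36). A second, dimmer JMJD2C probe at 7160372 to 7160431 showed −0.13 in the JMJD2C shRNA arm and −0.36 in the JAK2 shRNA arm, and the mean of both JMJD2C probes in the JMJD2C shRNA arm, −0.31, missed the limit. JAK2 showed −0.36 ± 0.09 in the JMJD2C shRNA arm (adjusted p = 0.000614, below the 0.5 limit). JMJD2C showed 0.08 ± 0.16 in the JAK2 shRNA arm. With the inhibitor JAK2 was at −0.13 (adjusted p = 0.0655) and JMJD2C at −0.20 (adjusted p = 0.0222, lower on 7 of 8 arrays), both below the 0.5 limit.

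**Figure D1:**
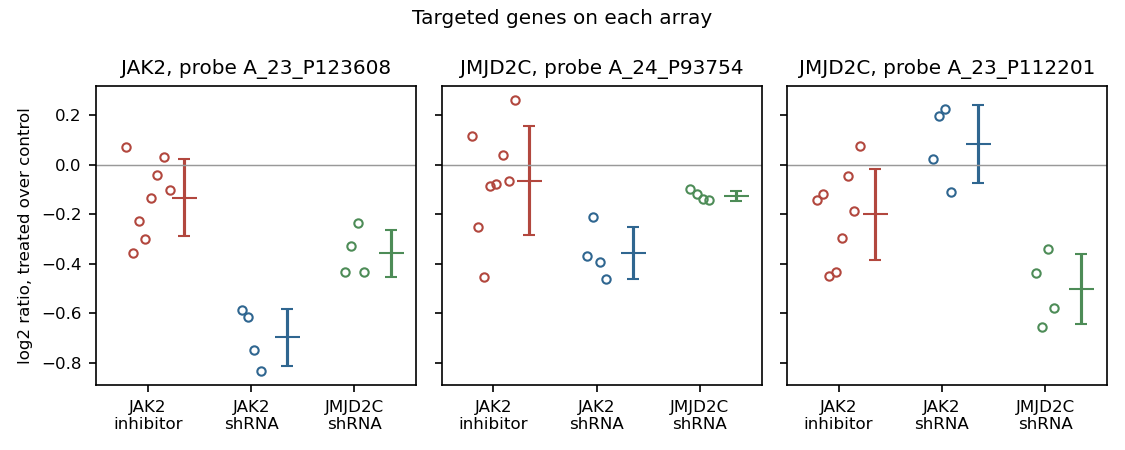
Log2 ratio of treated over control (y axis) for JAK2 and JMJD2C by arm (x axis), with 1 point per array and the mean ± SD as a bar. JAK2 lay below 0 on 4 of 4 arrays of each shRNA arm, and JMJD2C at its brightest probe on 4 of 4 arrays of the JMJD2C shRNA arm. The second JMJD2C probe, in its own panel, lay below 0 on 4 of 4 arrays of each shRNA arm.

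The comparison of the inhibitor with DMSO asks which genes depend on JAK2 activity. Among genes with a symbol and the same sign on every array, the largest fall was that of MYC, the transcription factor that drives ribosome biogenesis. Its mean was −1.81 (SE 0.149, n = 8 arrays, adjusted p = 8.35e-05). MYC was already at −1.70 at 0.5 h and lay between −2.89 and −1.33 throughout, while its 2 further probes stood at −0.11 and 0.11. SOCS3 and CISH, feedback inhibitors of cytokine receptors that STAT proteins switch on, fell by 1.35 (SE 0.114, adjusted p = 8.94e-05) and 1.37 (SE 0.182, adjusted p = 0.000570). A second SOCS3 probe stood at 0.00 and a second CISH probe at −0.04. NFIL3, a transcription factor induced by interleukins, fell by 1.52 (SE 0.175, adjusted p = 0.000324), and HK2, the hexokinase of the first step of glycolysis, by 1.37. VASP (−1.33) and PALLD (−1.33), which organise actin, and MOB3C (−1.64), AGAP1 (−1.35, with a second probe at 0.01) and RAB6B (−1.34) also fell. H2AC6, a histone H2A gene, rose most (1.54, SE 0.0813, adjusted p = 9.26e-06), though its second probe was at 0.20. DHRS2 (1.48), a short-chain dehydrogenase, and the histone H2A genes H2AC19 (1.31) and H2AC7 (0.95) rose as well. LYRM9, RNU12, APOLD1, SERTAD4-AS1, ATF7IP2 and PAX4 rose by 0.93 to 1.21, with second probes of ATF7IP2 and PAX4 at 0.03. Relative to the 0.5 h array, the arrays from 4 h on stood at 0.06 for MYC, 0.07 for SOCS3, 0.15 for VASP, −0.10 for H2AC19, 0.31 for JUN and 0.32 for CD274, so for these genes a change by 0.5 h and a dye bias cannot be told apart. In all, 1133 of 19518 genes changed, 452 higher and 681 lower. The 8 arrays lay on 2 slides, and with slide as a random block (correlation 0.13) 1113 genes were called. The fixed slide term used for the trend below was not applied to this mean. The split turned with the scanner software's own normalised values, at 1953 higher and 1476 lower of 3429, and with median centring only 23 genes were called, 2 higher and 21 lower. Array by array the count ran from 939 to 1478 when 1 array was left out. On the arrays from 4 h on minus the 0.5 h array, 895 genes were called, and 392 of the 1133 were among them. That subtraction cancels a dye bias equal on all arrays, but also a change already present at 0.5 h.

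Among STAT6 targets, the genes that interleukins 4 and 13 switch on, 0 rose, 8 fell and 6 of 14 did not pass (median −0.75, camera adjusted p = 0.000164, adjusted p = 0.497 with an estimated correlation). CCL17, a chemokine that attracts T cells, fell by 1.48, IL4I1 by 1.16, BATF3 by 0.81 and IL4R, the interleukin 4 receptor, by 0.76. Of 16 JAK-STAT targets 4 fell, CISH, SOCS3 and MYC among them, 0 rose and 12 did not pass (adjusted p = 0.000226, adjusted p = 0.258 with an estimated correlation). Of 21 PMBL signature genes 8 fell, among them MAL (−0.75) and CD274 (−0.53, the ligand of the PD-1 receptor, −0.49 and not called without the 2 h array), 0 rose and 13 did not pass (adjusted p = 0.00474, adjusted p = 0.258 with an estimated correlation). Interferon response genes fell, with 0 higher, 10 lower and 20 of 30 not passed (median −0.34, adjusted p = 3.87e-05, adjusted p = 0.522 with an estimated correlation), led by IFI44L (−1.29), XAF1 (−1.06) and USP18 (−0.91). Of 28 genes of MYC and ribosome biogenesis 0 rose, 10 fell and 18 did not pass (median −0.38, adjusted p = 8.73e-06, adjusted p = 0.522 with an estimated correlation), among them RRS1 (−1.07), NOP16 (−0.94) and SRM (−0.64).

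Plasma cell genes fell with the inhibitor, at 1 higher (CD38, 0.70), 6 lower (FKBP11 −0.70, JCHAIN −0.58 and PRDM1 −0.54 among them) and 7 of 14 not passed (adjusted p = 0.000711, adjusted p = 0.382 with an estimated correlation). Hypoxia and glycolysis genes had 5 lower, HK2, PFKFB4 (−0.70), P4HA1 (−0.57), BNIP3 (−0.55) and ENO1 (−0.52), 0 higher and 13 of 18 not passed (adjusted p = 0.00474, adjusted p = 0.497 with an estimated correlation). Mitochondrial ribosome genes had 4 lower, MRPL12 (−0.61), MRPL19, MRPS2 and MRPS12, 0 higher and 19 of 23 not passed (adjusted p = 0.000226, adjusted p = 0.520 with an estimated correlation). Genes for cytosolic ribosomal proteins rose, with 4 higher, RPS27 (0.68) and RPS2 (0.54) among them, 0 lower and 20 of 24 not passed (median 0.42, adjusted p = 2.38e-08, adjusted p = 0.497 with an estimated correlation). With the scanner software's values their median was 0.08 and the list was not called. Replication-dependent histones rose too, with H2AC6, H1-2 (0.79) and H2BC12 (0.71) higher, 0 lower and 8 of 11 not passed (adjusted p = 0.0147, adjusted p = 0.497 with an estimated correlation). Cell cycle genes (30, median −0.22, adjusted p = 0.000164), cholesterol synthesis genes (20, median −0.14, adjusted p = 0.0120) and heat shock genes (11, median −0.24, adjusted p = 0.0245) shifted down with no gene past the limit, as for PLK1 (−0.35), IDI1 (−0.44) and HSP90AA1 (−0.46). With an estimated correlation these were at adjusted p = 0.522, adjusted p = 0.532 and adjusted p = 0.590. With median centring their medians were 0.00, 0.12 and 0.05, and none was called. ATF4 stress response genes had 4 higher, ATF4 (0.88), CHAC1 (0.87), PSAT1 (0.84) and ASNS (0.66, with a second probe at −0.06), 1 lower, GDF15 (−0.86), and 16 of 21 not passed (adjusted p = 0.622). Calls lost without 1 array were those of PFKFB4 (−0.44), P4HA1 (−0.45) and BNIP3 (−0.44) without the 4 h array, MRPS12 (−0.49) without the 24 h array, PRDM1 (−0.44) without the 2 h array, and ENO1 (−0.40), MRPL19 (−0.50) and MRPS2 (−0.46) without the 48 h array. PFKFB4 was also lost without the 2, 6, 16, 24 or 48 h array (−0.64 to −0.74), ENO1 without the 16 or 24 h (−0.50 and −0.49), MRPL19 without the 24 h (−0.49) and MRPS2 without the 6, 16 or 24 h (−0.47 to −0.49). Adjusted over the list alone, each list kept the counts given, except that 2 genes of the ATF4 list were lower.

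**Figure D2:**
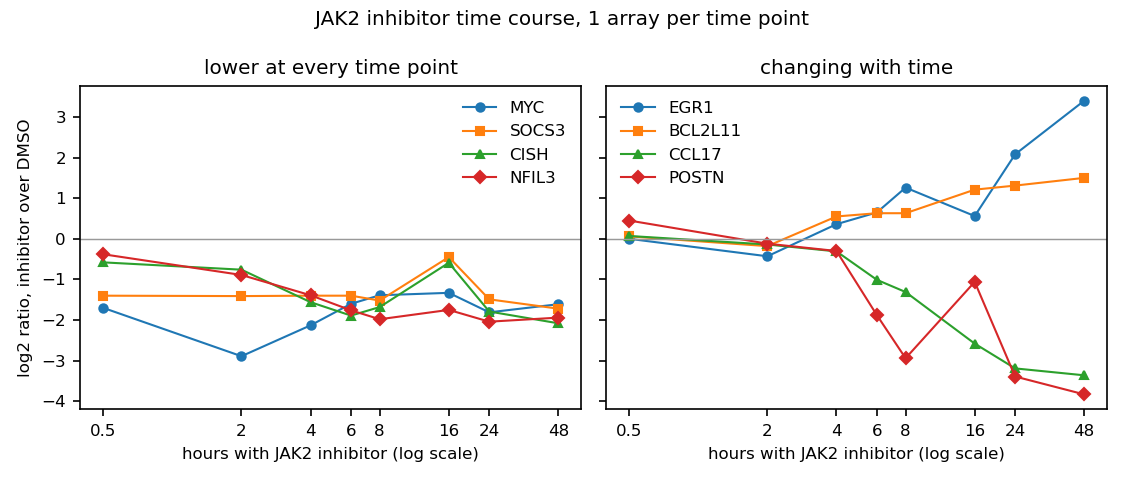
Log2 ratio of inhibitor over DMSO (y axis) against hours of treatment (log axis), with 1 line per gene and 1 array per time point. MYC, SOCS3, CISH and NFIL3 were lower at every time point, while EGR1 and BCL2L11 climbed and CCL17 and POSTN fell with time.

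The time trend asks which genes kept moving as the inhibitor acted, as the fitted change from 0.5 to 48 h. CCL17 fell by 4.05 over the course (SE 0.515, adjusted p = 0.0150), from 0.07 at 0.5 h to −3.36 at 48 h. POSTN, the matrix protein periostin, fell by 4.39 (SE 0.818, adjusted p = 0.0359), though treated cells were above background on only 6 of 8 arrays. RAB6B (−3.37), HOMER2 (−3.07), EFEMP1 (−2.79), SLC37A3 (−2.60), RNF125 (−2.43, with a second probe at −0.05) and KMO (−2.15), an enzyme of tryptophan breakdown, fell as well. EGR1, an immediate early transcription factor, rose by 3.24 (SE 0.690, adjusted p = 0.0471) and BCL2L11 (BIM), which promotes apoptosis, by 1.73 (SE 0.247, adjusted p = 0.0225) (4 further BCL2L11 probes at 0.27 to 0.80). RGS1 (2.34) and RGS13 (1.70), which shut off G protein signals, rose with them, as did SERTAD4-AS1, TCTN1, SMIM14 (control above background on 5 of 8 arrays), LYRM9 and P4HA2 (second probe at 0.53) by 1.48 to 2.03. In all 388 of 19518 genes changed, 162 higher and 226 lower, and the split turned with no background correction (538 higher, 417 lower), array weights (488, 343), the rank of time (863, 745) and the scanner software's values (408, 391). Limma called 0 with slide as a fixed block (1644 at unadjusted p below 0.05), and 0 with median centring (322 at unadjusted p below 0.05). Of 100 orders of the times that kept each array on its slide, the real one included, 14 gave as many calls, up to 2284. There were 0 calls without the 24 h array (3416 at unadjusted p below 0.05) and 0 without the 48 h array (2791), and 87 without the 2 h, 118 without the 4 h, 185 without the 6 h, 118 without the 8 h, 677 without the 16 h and 2451 without the 0.5 h array.

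Genes of MYC and ribosome biogenesis fell further with time (median −0.66, camera adjusted p = 3.77e-12, adjusted p = 0.234 with an estimated correlation), NOLC1 (−1.17), CDK4 (−0.94) and GAR1 (−0.64) past the limit, 0 higher and 25 of 28 not passed. STAT6 targets fell (median −1.03, adjusted p = 7.04e-06, adjusted p = 0.234 with an estimated correlation), with CCL17, HOMER2, NFIL3 (−1.71) and BATF3 (−1.67) called, 0 higher and 10 of 14 not passed. Cell cycle genes fell (median −0.50, adjusted p = 2.35e-09, adjusted p = 0.234 with an estimated correlation), with CDC20 (−1.06), PLK1 (−0.90, with a second probe at −0.71), MCM7 (−0.83) and AURKA (−0.68) called, 0 higher and 26 of 30 not passed. Interferon response genes fell as a list (median −0.54, adjusted p = 2.82e-05, adjusted p = 0.447 with an estimated correlation), with 2 lower, USP18 (−1.75) among them, IFIT2 (1.38, with a second probe at 0.28) higher and 27 of 30 not passed. NF-kB targets rose (median 0.28, −0.14 with median centring, adjusted p = 0.0343, adjusted p = 0.447 with an estimated correlation) with BCL2A1 (0.78) called, 0 lower and 20 of 21 not passed. Cytosolic ribosomal protein genes rose (median 0.38, adjusted p = 8.27e-06, adjusted p = 0.447 with an estimated correlation) with RPS27 (0.77) called, 0 lower and 23 of 24 not passed. ER chaperones (adjusted p = 0.00164) fell with CALR (−0.98) called and cholesterol synthesis genes (adjusted p = 0.00452) with DHCR7 (−1.35) called, both at adjusted p = 0.447 with an estimated correlation. Heat shock (adjusted p = 3.17e-06), mitochondrial ribosome (adjusted p = 7.08e-05) and ATF4 stress response genes (adjusted p = 0.00164) fell with no gene called. With an estimated correlation these were at adjusted p = 0.234, adjusted p = 0.447 and adjusted p = 0.472. Adjusted over the list alone, 18 MYC genes, 8 STAT6 targets, 12 cell cycle genes, 8 heat shock genes, 7 mitochondrial ribosome genes, 6 ER chaperones, 4 interferon response genes and 2 cholesterol genes were lower, while 6 NF-kB targets, 7 ribosomal protein genes and 1 each of the STAT6, interferon and ER chaperone lists were higher.

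The JAK2 shRNA arm asks what changed when the shRNA against JAK2 was induced, with JAK2 mRNA at 0.617 of the uninduced level. HILPDA, a lipid droplet protein induced by hypoxia, rose most, by 2.60 (SE 0.139, n = 4 arrays, adjusted p = 1.50e-06). GPER1 (2.50), a membrane estrogen receptor, the potassium channel subunit KCNMB2 (2.36), the vasodilator peptide gene ADM (2.33), NRN1 (2.25), ATP4A (2.23) and PIGZ (2.13) rose with it, as did SERTAD4-AS1, DUSP26 and GPR146 by 1.93 to 2.13. CXCL9, a chemokine induced by interferon gamma, fell most, to −2.56 (SE 0.157, adjusted p = 2.59e-06). UBD (−2.02), MIR155HG (−1.98), the host transcript of microRNA 155, the interferon-induced genes XAF1 (−1.97) and IFIT3 (−1.87), and CCL17 (−1.86) fell as well. So did MALAT1 (−2.10), a nuclear noncoding RNA with 1 further probe the other way, NBPF11 (−1.82, with a second probe at 0.10), HNRNPA0 (−1.82) and NBPF10 (−1.80). MYC fell by 1.05 (adjusted p = 1.77e-06), though its further probes stood at −0.04 and −0.03, and with median centring it stood at 0.15, which was −0.28 relative to the median of all genes. SOCS3 (−0.46) and CISH (−0.21) did not pass the limit. In all 4020 of 21031 genes changed, 2084 higher and 1936 lower. Without 1 array the count was 3720 to 4491, and with median centring it was 10197, of which 9750 were higher.

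Genes of MYC and ribosome biogenesis fell in the JAK2 shRNA arm, with 0 higher, 21 lower and 5 of 26 not passed (median −0.91, camera adjusted p = 2.02e-11). NOP16 (−1.54), SRM (−1.45) and RRS1 (−1.72) were among the lower genes, and with median centring the list's median was 0.15. Heat shock genes fell, with 0 higher, 7 lower and 4 of 11 not passed (adjusted p = 1.33e-05, adjusted p = 0.0809 with an estimated correlation), HSPA8 (−1.58) and HSP90AA1 (−1.32) among them, and their median turned to 0.18 with median centring. NF-kB targets had 1 higher, RELB (0.92), 8 lower, TNF (−1.66), REL (−1.59) and IER3 (−1.10) among them, and 12 of 21 not passed (adjusted p = 3.74e-05). Their median of −0.47 turned to 0.45 with median centring. Interferon response genes had 0 higher, 17 lower and 14 of 31 not passed (median −0.61, 0.31 with median centring, adjusted p = 2.37e-06, adjusted p = 0.317 with an estimated correlation), GBP1 (−1.73) and IFIT1 (−1.71) among them. PMBL signature genes had 2 higher, PIM2 (0.77) and TLE1 (0.57), 8 lower, FCER2 (−1.44) and BATF3 (−1.38) among them, and 11 of 21 not passed (median −0.25, 0.49 with median centring, adjusted p = 0.0140, adjusted p = 0.317 with an estimated correlation). ER chaperones had 2 higher, EDEM1 (0.75) and DNAJB9 (0.60), 7 lower, HSPA5 (−0.86, 0.07 with median centring) among them, and 5 of 14 not passed (median −0.48, 0.56 with median centring, adjusted p = 0.00348, adjusted p = 0.362 with an estimated correlation). Mitochondrial ribosome genes had 0 higher, 9 lower, MRPL12 (−1.03) among them, and 14 of 23 not passed (median −0.40, 0.58 with median centring, adjusted p = 1.57e-06). Oxidative phosphorylation genes had 1 higher, UQCRH (0.52), 7 lower, CYCS (−0.70, 0.20 with median centring) among them, and 14 of 22 not passed (median −0.22, 0.91 with median centring, adjusted p = 0.000797, adjusted p = 0.198 with an estimated correlation). With median centring this list was called in the opposite direction, at 0.48 above the median of all genes (camera adjusted p = 0.00735). By camera with an estimated correlation the MYC, NF-kB and mitochondrial ribosome lists were at adjusted p = 0.0441, 0.0441 and 0.0299.

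Cell cycle genes rose with the JAK2 shRNA, with 14 higher, 0 lower and 16 of 30 not passed (median 0.43, adjusted p = 0.000359), led by the mitotic genes BIRC5 (1.5), CCNB2 (1.29, with a second probe at −0.29) and PLK1 (1.22). By camera with an estimated correlation this list was at adjusted p = 0.0451. Hypoxia and glycolysis genes had 11 higher, BNIP3 (1.72) and PFKFB4 (1.39) among them, 0 lower and 9 of 20 not passed (median 0.52, adjusted p = 3.63e-05, adjusted p = 0.248 with an estimated correlation). Cytosolic ribosomal protein genes had 8 higher, RPL30 (0.73) and RPS14 (0.77) among them, 1 lower, RPL7 (−0.73), and 16 of 25 not passed (adjusted p = 0.00257, adjusted p = 0.0809 with an estimated correlation), and were not called with the scanner software's values (median 0.22). JAK-STAT targets had 3 higher, PIM1 (1.26), PIM2 and BCL6 (0.73), 4 lower, MYC, BCL2L1 (−0.82) and IRF1 (−0.67) among them, and 10 of 17 not passed (adjusted p = 0.523). STAT6 targets had 0 higher, 5 lower, CCL17, FCER2, BATF3, BCL2L1 and HOMER2, and 10 of 15 not passed (adjusted p = 0.202). ATF4 stress response genes had 7 higher, PSAT1 (1.09) and ATF4 (1.01) among them, 1 lower, WARS1 (−0.61), and 13 of 21 not passed (adjusted p = 0.0678). In the 9p24 segment UHRF2 (0.64) and RIC1 (0.62) rose, PUM3 (−1.35), CD274 (−0.78), JAK2 and RCL1 (−0.58) fell, and 18 of 24 genes did not pass (adjusted p = 0.902). With median centring RCL1 (0.46), WARS1 (0.42), RPL7 (0.40), HOMER2 (0.28), CD274 (0.09) and IRF1 (0.04) stood above 0, and without the 24 h array RCL1 (−0.49) and TLE1 (0.49) were not called. Adjusted over the list alone, the counts of each list were the same.

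The JMJD2C shRNA arm asks what changed when the shRNA against the demethylase was induced. Interferon-induced genes fell most: IFIT1, which binds foreign RNA, by 2.31 (SE 0.148, n = 4 arrays, adjusted p = 1.20e-05), IFI44L by 1.56, IFIT3 by 1.56, IFI44 by 1.44, XAF1 by 1.42 and EIF2AK2, the kinase activated by double-stranded RNA, by 1.44. MIR155HG (−1.42), SET (−1.42, with a second probe at 0.24) and UTP20 (−1.37) also fell, as did CDC42EP5 (−1.41, and −1.46 without the 96 h array, which was not called). KASH5, a linker of the nuclear envelope, rose by 1.54 (SE 0.113, adjusted p = 1.94e-05), with RAB37 (1.53), PIGZ (1.47), ADM (1.46), KCNMB2 (1.44), HILPDA (1.39), ATP4A, NRN1, RADIL and WNT5A (1.35). MYC fell by 0.82, though its further probes stood at −0.15 and 0.08 and the mean of all its probes was −0.30. In all 2592 of 21031 genes changed, 1250 higher and 1342 lower. Without 1 array the count was 1835 to 3222, lowest without the 72 h array, and with median centring it was 6622, of which 6443 were higher.

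Genes of MYC and ribosome biogenesis fell, with 0 higher, 19 lower and 7 of 26 not passed (median −0.73, camera adjusted p = 1.68e-10), SRM (−1.23) and NOP16 (−1.21) among them. Interferon response genes had 0 higher, 17 lower and 14 of 31 not passed (median −0.60, adjusted p = 4.20e-09, adjusted p = 0.199 with an estimated correlation), RSAD2 (−1.30) among them. Heat shock genes had 0 higher, 9 lower and 2 of 11 not passed (adjusted p = 3.52e-06, adjusted p = 0.0601 with an estimated correlation), HSPA8 (−1.24) and HSPH1 (−1.11) among them. ER chaperones had 0 higher, 9 lower, HSPA5 (−0.91) and CALR (−0.89) among them, and 5 of 14 not passed (median −0.65, 0.01 with median centring, adjusted p = 1.38e-05, adjusted p = 0.183 with an estimated correlation). NF-kB targets had 0 higher, 6 lower, TNF (−1.17) and CFLAR (−0.73) among them, and 15 of 21 not passed (median −0.27, 0.28 with median centring, adjusted p = 1.34e-05). Mitochondrial ribosome genes had 0 higher, 7 lower, MRPL12 (−1.15) among them, and 16 of 23 not passed (median −0.26, 0.32 with median centring, adjusted p = 5.24e-05). Oxidative phosphorylation genes had 1 higher, UQCRH (0.62), 2 lower, ATP5PF (−0.91, with a second probe at 0.11) and CYCS (−0.76), and 19 of 22 not passed (median −0.27, 0.46 with median centring, adjusted p = 8.68e-05, adjusted p = 0.126 with an estimated correlation). With median centring this list too was called in the opposite direction, at 0.21 above the median of all genes (camera adjusted p = 0.0409). By camera with an estimated correlation the MYC, NF-kB and mitochondrial ribosome lists were at adjusted p = 0.0400, 0.0322 and 0.0322. PMBL signature genes had 1 higher, IL4R (0.55), 4 lower, FCER2 (−1.07), CCL17 (−1.03), BATF3 (−0.90) and NFKB2 (−0.50), and 16 of 21 not passed (median −0.28, 0.30 with median centring, adjusted p = 0.0253, adjusted p = 0.321 with an estimated correlation). The p53 targets had 0 higher, 2 lower, BBC3 (−1.22, with −0.62 without the 72 h and −1.20 without the 96 h array, neither called) and PHLDA3 (−1.02), and 16 of 18 not passed (median −0.25, 0.37 with median centring, adjusted p = 0.0247, adjusted p = 0.141 with an estimated correlation). Cholesterol synthesis genes had 0 higher, 1 lower, MVD (−0.55, −0.35 and not called without the 72 h array), and 18 of 19 not passed (median −0.19, 0.46 with median centring, adjusted p = 0.0173, adjusted p = 0.342 with an estimated correlation).

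Cell cycle genes rose with the JMJD2C shRNA, with 10 higher, CENPA (0.89) and PLK1 (0.88) among them, 1 lower, MCM4 (−0.52), and 19 of 30 not passed (median 0.34, adjusted p = 0.000400). Hypoxia and glycolysis genes had 7 higher, ADM and BNIP3 (0.86) among them, 0 lower and 13 of 20 not passed (adjusted p = 0.000445, adjusted p = 0.293 with an estimated correlation). ATF4 stress response genes had 5 higher, PSAT1 (0.93), CHAC1 (0.69), ATF4 (0.64, with a second probe at 0.06), DDIT3 (0.56) and ASNS (0.53), 0 lower and 16 of 21 not passed (adjusted p = 0.00593, adjusted p = 0.0601 with an estimated correlation). Cytosolic ribosomal protein genes had 6 higher, RPS2 (0.74) and RPS14 (0.60) among them, 0 lower and 19 of 25 not passed (adjusted p = 1.34e-05). Replication-dependent histones had 3 higher, H2AC6 (0.66), H1-2 (0.61) and H4C8 (0.51, 0.45 and not called without the 72 h array), 0 lower and 7 of 10 not passed (adjusted p = 0.0362, adjusted p = 0.320 with an estimated correlation). Neither of these lists was called with the scanner software's values, with medians of 0.13 and 0.22. By camera with an estimated correlation the cell cycle and cytosolic ribosomal protein lists were at adjusted p = 0.0400 and 0.0322. Among H3K9 and heterochromatin genes, EHMT1 (0.61, with a second probe at 0.03), a methyltransferase, and KDM3A (0.61), a demethylase, rose, JMJD2C and TRIM28 (−0.50) fell, and 15 of 19 did not pass (adjusted p = 0.942). In the 9p24 segment ERMP1 (0.55) and UHRF2 (0.51) rose, PUM3 (−0.98), RCL1 (−0.54) and JMJD2C fell, and 19 of 24 did not pass (adjusted p = 0.804). Calls lost without the 72 h array were those of TRIM28 (−0.29), NFKB2 (−0.36), MCM4 (−0.48), ERMP1 (0.48) and UHRF2 (0.49, and also 0.49 without the 96 h array), while ASNS (0.49) was lost without the 48 h array and RCL1 (−0.50) without the 24 h array. With median centring RCL1 (0.10) and TRIM28 (0.06) stood above 0. Adjusted over the list alone, the counts of each list were the same.

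**Figure D3:**
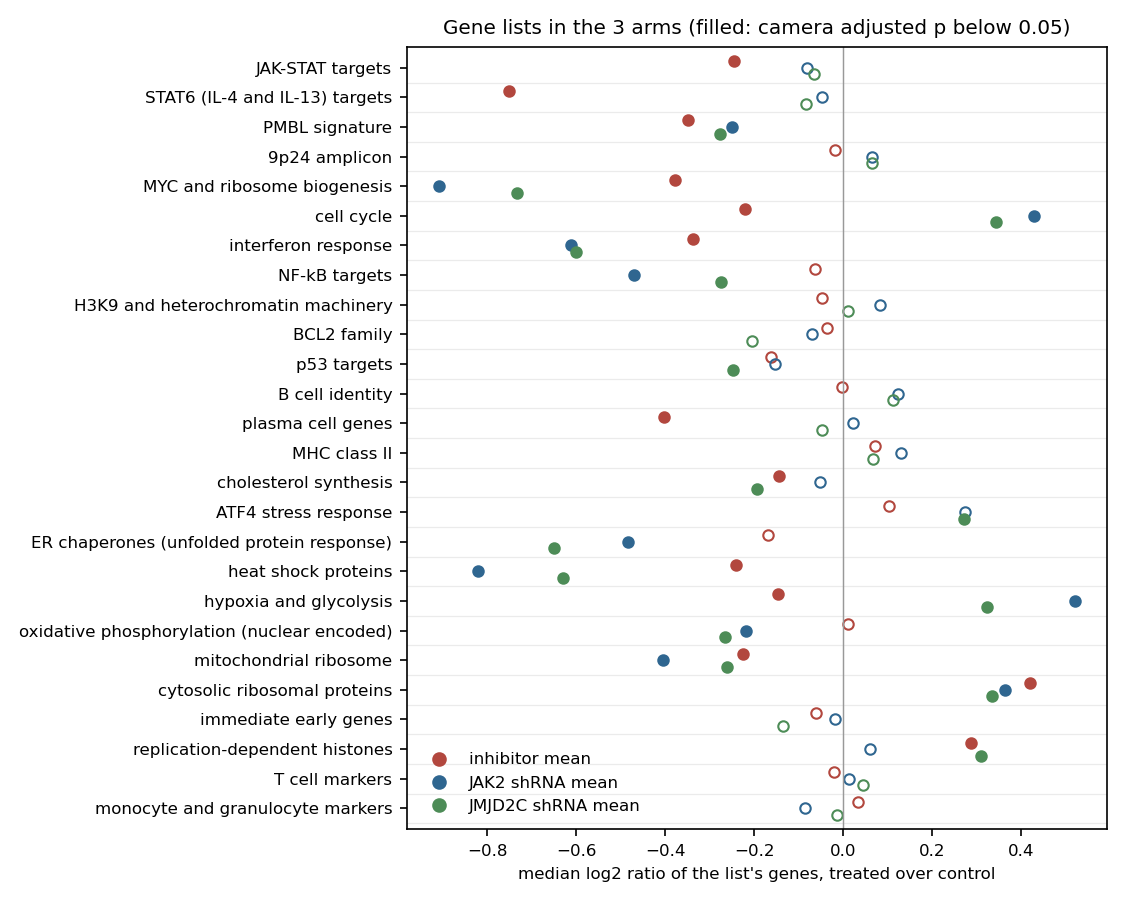
Median log2 change of each gene list (x axis) in the inhibitor arm and both shRNA arms, with the lists along the y axis and filled points where the camera adjusted p was below 0.05. Genes of MYC and ribosome biogenesis lay below 0 in all 3 arms (at 0.15 in the JAK2 shRNA arm with median centring), while cell cycle genes (0.00 with median centring) and hypoxia genes lay below 0 with the inhibitor, and both lay above 0 with both shRNAs.

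The comparison of the 2 shRNA arms asks which changes the arms share. HILPDA (2.60 with the JAK2 shRNA and 1.39 with the JMJD2C shRNA), ADM (2.33 and 1.46), KCNMB2 (2.36 and 1.44) and NRN1 (2.25 and 1.37) rose in both. IFIT1 (−1.71 and −2.31), IFIT3 (−1.87 and −1.56), XAF1 (−1.97 and −1.42), CXCL9 (−2.56 and −0.97) and MIR155HG (−1.98 and −1.42) fell in both. UTP20 (−1.62 and −1.37) and RRS1 (−1.72 and −1.19), which act in ribosome assembly, fell in both too. MYC (−1.05 and −0.82 at its brightest probe), HSPA8 (−1.58 and −1.24) and TNF (−1.66 and −1.17) fell in both, and BIRC5 (1.5 and 0.73) and PLK1 (1.22 and 0.88) rose in both. In all 1929 genes were called the same way, 1034 higher and 895 lower, where 123.9 and 123.5 would share a call if the arms were independent, and 2 were called opposite ways. These were 74.42% of the calls of the JMJD2C shRNA arm and 47.99% of those of the JAK2 shRNA arm. Without 1 array the number was 1550 to 2249, with the scanner software's values 3821 (2277 higher, 1544 lower), and with median centring 6156, of which 6082 were higher. The sizes of the 21031 genes correlated at r = 0.811 (Spearman 0.816), over genes that are not independent replicates. Of the shared calls 316 were also called the same way with the inhibitor and 11 the opposite way, of 1923 tested there. Of all genes tested with the inhibitor 5.8% were called in either direction. Over 19117 genes the inhibitor mean correlated with the JMJD2C shRNA mean (r = 0.491) about as much as with the JAK2 shRNA mean (r = 0.473). All 3 arms had the same dye orientation, so a shared dye bias could add to this overlap.

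**Figure D4:**
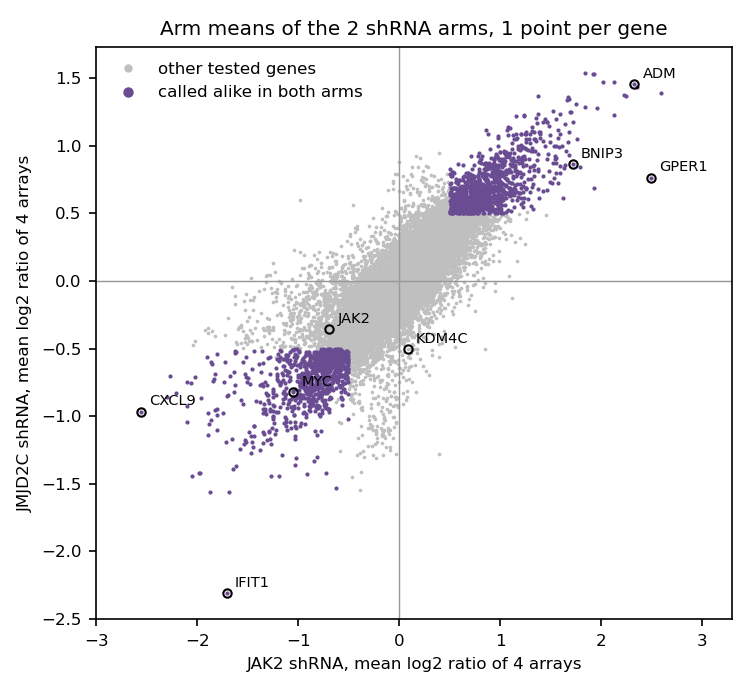
Mean log2 change with the JMJD2C shRNA (y axis) against that with the JAK2 shRNA (x axis), with 1 point per gene and genes called alike in both arms in purple. The 1929 genes called alike lie in the upper right and lower left.

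The JAK2 shRNA minus the JMJD2C shRNA gives what set the arms apart, though each arm lay on its own slide, so arm and slide cannot be told apart. GPER1 was 1.73 higher with the JAK2 shRNA (SE 0.183, n = 4 and 4 arrays, adjusted p = 0.00195), with the nuclear import receptor IPO7 (1.67), ANKRD30BP2, GPR146 (1.24), HILPDA (1.21), GATM, PDLIM2, SIPA1L3, WNT10A and LSM6 (0.99). CXCL9 was 1.60 lower (SE 0.222, adjusted p = 0.00399), with the DNA damage kinase ATM (−1.58), the guanylate-binding protein GBP5 (−1.42), the lymphoid transcription factor IKZF1 (−1.34), KLC3, UBD (−1.31), CLUH, MAGOH, SIAE and FUT6 (−1.19). Further probes of PDLIM2 (−0.15 and 0.01), IKZF1 (0.06 and 0.16), CLUH (0.12), SIAE (−0.30 and 0.01) and FUT6 (0.02) did not all go the same way. JMJD2C was 0.59 higher with the JAK2 shRNA (adjusted p = 0.00707), though its second probe was lower (−0.23, adjusted p = 0.0468), while JAK2, at −0.34 (adjusted p = 0.0225), stayed below the limit. Hypoxia and glycolysis genes were higher with the JAK2 shRNA, with 5 higher, ADM (0.87), BNIP3 (0.85), PFKFB4 (0.78), HK2 (0.77) and P4HA1 (0.59), 0 lower and 15 of 20 not passed (median 0.24, camera adjusted p = 0.00129, adjusted p = 0.484 with an estimated correlation). Genes of MYC and ribosome biogenesis were lower, with RRS1 and MRTO4 (−0.53 each) called, 0 higher and 24 of 26 not passed (median −0.21, 0.20 with median centring, adjusted p = 6.33e-05, adjusted p = 0.260 with an estimated correlation). Cell cycle genes were higher, with BIRC5 (0.77) called, 0 lower and 29 of 30 not passed (adjusted p = 0.0118, adjusted p = 0.254 with an estimated correlation). Mitochondrial ribosome genes were lower with 0 called (median −0.09, 0.30 with median centring, adjusted p = 0.0255, adjusted p = 0.254 with an estimated correlation). In all 824 of 21031 genes differed, 286 higher and 538 lower. With median centring the split turned, at 3555 higher and 387 lower of 3942, and 524 of the 824 were still called. Without the 72 h JAK2 shRNA array ADM (0.80), PFKFB4 (0.76), HK2 (0.72), P4HA1 (0.53), RRS1 (−0.49), MRTO4 (−0.49) and SIPA1L3 (0.95) were not called, and each of them but P4HA1 also lost its call without at least 1 other array. Without 1 array the count was 539 (without the 72 h array of the JAK2 shRNA) to 1097.

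Within the shRNA arms, the time trend asks whether changes grew from 24 to 96 h. By limma 0 of 21031 genes passed in either arm, with 1455 at unadjusted p below 0.05 in the JAK2 shRNA arm and 943 in the JMJD2C shRNA arm. With array weights 618 passed in the 2 arms together, 154 higher and 464 lower. Interferon response genes drifted further down with the JMJD2C shRNA (median −0.44, camera adjusted p = 2.83e-09, adjusted p = 0.640 with an estimated correlation), as for IFIT1 (−0.94), MX1 (−0.73) and IFIT3 (−0.67), and 6 were lower adjusted over the list alone. Replication-dependent histones drifted down with the JAK2 shRNA (median −0.20, adjusted p = 0.00423, adjusted p = 0.442 with an estimated correlation), with 0 called.

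Inhibitor and JAK2 shRNA were compared at the 2 times they share, 24 and 48 h, to ask where their changes differ. The arms lay on different slides and only the shRNA arm had doxycycline, so neither can be told apart from the treatment. The genes named are JAK2 and examples from the lists, not chosen as the largest differences. BIRC5, an inhibitor of apoptosis needed in mitosis, was 2.14 lower with the inhibitor, PLK1 1.97 lower and CCNB2 1.63 lower. ADM (−2.23), HK2 (−2.15) and BNIP3 (−2.05) were lower as well, as were NFIL3 (−2.30), CISH (−1.68), SOCS3 (−1.15), PIM1 (−0.97) and MYC (−0.63). Second probes of CCNB2 (0.63) and SOCS3 (0.11) went the other way, that of CISH was at −0.18, and further MYC probes stood at −0.13 and 0.07. The MYC difference was not called without the 24 h inhibitor array (−0.53) or the 48 h shRNA array (−0.49). EGR1 (2.50) and the inflammatory genes CCL4 (1.56) and TNF (1.11) were higher with the inhibitor, and JAK2 mRNA was 0.57 higher (adjusted p = 0.00652), though 0.50 and not called without the 24 h inhibitor array. In all 3766 of 20662 genes differed, 1853 higher and 1913 lower, and 2599 to 4111 without 1 array, lowest without the 48 h inhibitor array. With median centring 6740 differed, 871 higher and 5869 lower.

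Cell cycle genes were lower with the inhibitor than with the JAK2 shRNA, with 0 higher, 18 lower and 12 of 30 not passed (median −0.71, camera adjusted p = 4.80e-11, adjusted p = 0.331 with an estimated correlation). Hypoxia and glycolysis genes had 0 higher, 14 lower and 6 of 20 not passed (median −0.84, adjusted p = 4.02e-08, adjusted p = 0.337 with an estimated correlation). ATF4 stress response genes had 1 higher, WARS1 (0.66), 11 lower, CEBPB (−1.57, with a second probe at −0.01) and PSAT1 (−1.03) among them, and 10 of 22 not passed (adjusted p = 6.60e-07, adjusted p = 0.331 with an estimated correlation). JAK-STAT targets had 0 higher, 8 lower and 9 of 17 not passed (adjusted p = 0.00441, adjusted p = 0.331 with an estimated correlation). STAT6 targets had 2 higher, FCGR2B (0.95) and FCER2 (0.79), 8 lower, MAL (−1.55) among them, and 5 of 15 not passed (adjusted p = 0.0108, adjusted p = 0.686 with an estimated correlation). Plasma cell genes had 0 higher, 4 lower, JCHAIN (−1.64), XBP1 (−1.10), CREB3L2 and PRDM1, and 10 of 14 not passed (adjusted p = 0.0108, adjusted p = 0.686 with an estimated correlation). NF-kB targets had 11 higher, 0 lower and 10 of 21 not passed (median 0.53, −0.01 with median centring, adjusted p = 2.02e-06, adjusted p = 0.331 with an estimated correlation). Oxidative phosphorylation genes had 6 higher, NDUFB3 (0.99) among them, 0 lower and 17 of 23 not passed (median 0.35, −0.12 with median centring, adjusted p = 0.00289, adjusted p = 0.515 with an estimated correlation). Cytosolic ribosomal protein genes had 10 higher, RPS16 (0.80) among them, 1 lower, RPL30 (−0.69), and 14 of 25 not passed (median 0.39, −0.04 with median centring, adjusted p = 0.0108, adjusted p = 0.331 with an estimated correlation). Genes of MYC and ribosome biogenesis had 6 higher, NHP2 (0.81) and NME1 (0.75) among them, 2 lower, MYC and LDHA (−0.58), and 18 of 26 not passed (median 0.29, −0.20 with median centring, adjusted p = 0.0108, adjusted p = 0.686 with an estimated correlation). Without the 24 h shRNA array FCGR2B (0.86) and XBP1 (−1.17) were not called, nor without the 48 h shRNA array XBP1 (−1.04) and RPL30 (−0.38), and RPL30 was not called without the 24 h (−0.84) or 48 h (−0.53) inhibitor array either. Adjusted over the list alone, the plasma cell list had 1 gene higher and the ribosomal list 11, and the other lists named here kept their counts.

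**Figure D5:**
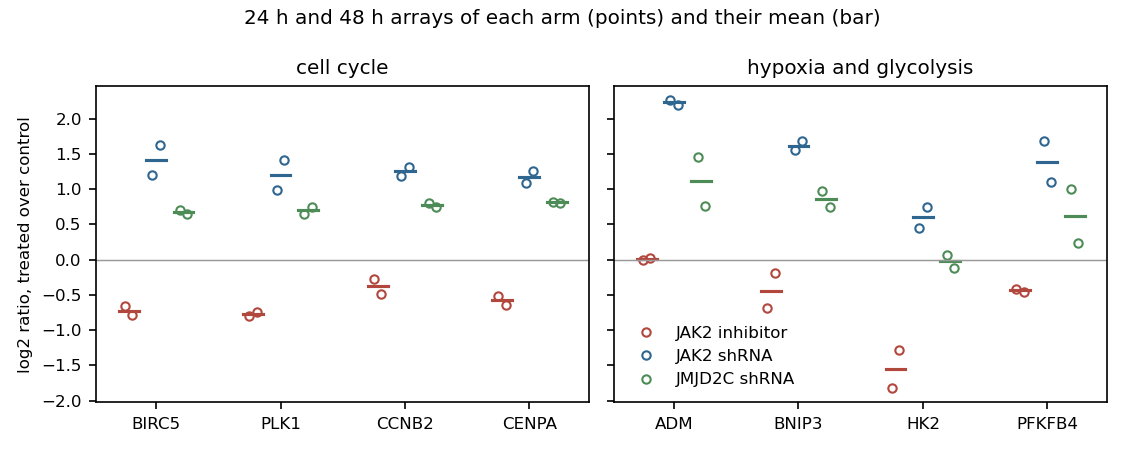
Log2 ratio of treated over control (y axis) at 24 and 48 h for cell cycle genes BIRC5, PLK1, CCNB2 and CENPA and hypoxia genes ADM, BNIP3, HK2 and PFKFB4 in each arm (x axis), with 1 point per array and bars at the mean. The points of BIRC5, PLK1, CCNB2 and CENPA lay lower with the inhibitor than with the JAK2 shRNA.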

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

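The orders within slides and the variance of the 0.5 h array were tests chosen after the results were seen.

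The shRNA arms resembled each other far more than independent calls would: 1929 genes were called alike and the arm means correlated at r = 0.811. Dye bias of equal size on all arrays is argued against as the whole cause. The variance of the 0.5 h inhibitor array was only 0.417 of the covariance of the arm means. The correlation of the arm means given that array was 0.762, but 1 array with its own noise cannot take out all of a shared bias. That correlation thus decides nothing. A part stays open: the arm means correlated with the 0.5 h array (0.431 and 0.505) about as much as with the 24 and 48 h arrays (0.412 and 0.465), and a dye bias of the shRNA arrays alone was not tested. Doxycycline, given to both arms and to neither control, stays open: 0.6779 of the genes called alike moved the same way with the inhibitor (24 and 48 h minus 0.5 h, no doxycycline), against 0.561 of all tested genes. That share lay between the bounds set for and against it, and with no arm on doxycycline alone, a response that JAK2 and JMJD2C loss share cannot be told apart from one to doxycycline.

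The difference between the shRNA arms, 824 genes, was larger than in any of the other 34 splits of the 8 arrays into 4 and 4. Only 1 of 35 splits, the real one, gave as many, and the highest other gave 401. No share smaller than 1 of 35 was possible, and the real split alone follows both arm and slide. The splits thus do not exclude chance. Slide stays open, since 0 slides held arrays of both arms, so arm and slide cannot be told apart. The shRNA target, the difference the design names, was not tested apart from slide.

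The inhibitor trend called 388 genes, and 1 of 100 random orders of the times, the real one included, gave as many, with 0 in the highest other. A chance order over all arrays is thus argued against, though these orders also mix the slides. A step between the slides stays open: of 100 orders that kept each array on its slide, 14 gave as many, the real one included, and the highest other gave 2284. The share of called genes that kept their sign with slide as a block was 1 (388 of 388), but this decides nothing, since the median share over the other orders within slides was also 1. With the block the median ratio of sizes was 0.873, the median SE rose from 0.177 to 0.283, and no gene passed. The early times lay on the first slide and the late times on the second, so a late response to the inhibitor cannot be told apart from slide.

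Of 75 tests for an array far from the others of its arm, 3 went beyond the limit. Most genes tested were picked for a large change with the same sign on every array, and the arrays are a time course. The number that chance would give is thus not known. SOCS3 with the inhibitor was −0.454 at 16 h against −1.72 to −1.40 at the other times. CXCL9 with the JAK2 shRNA was −2.16 at 96 h against −2.76 to −2.66. The correlation with the rest of the arm was 0.862 for the 24 h JAK2 shRNA array against 0.954 to 0.972 for the others. The Agilent spike-in controls, which the comparisons do not use, had a median log2 Cy5 over Cy3 ratio of 3.58 to 4.83 on the inhibitor arrays, against 0.619 to 1.815 on the JAK2 shRNA arrays and −0.505 to 1.145 on the JMJD2C shRNA arrays. Their slopes were 0.00552 to 0.161 on the inhibitor arrays against 0.809 to 0.890 on the shRNA arrays, and whether the mix went into both channels of the inhibitor arrays is not known, so what the ratio means is in doubt.

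Genes that differed between the JAK2 and JMJD2C shRNA arms, as JAK2 minus JMJD2C, were GPER1 (1.73), IPO7 (1.67), ANKRD30BP2 (1.35), GPR146 (1.24), HILPDA (1.21), GATM (1.05), PDLIM2 (1.05), SIPA1L3 (1.03), WNT10A (1.01), LSM6 (0.992), ADM (0.875), BNIP3 (0.854), HK2 (0.775), BIRC5 (0.774), PIM2 (0.709), EGR1 (0.698, though 0.602 and not called without the 72 h JAK2 shRNA array), KDM4C (0.586, though its second probe was at −0.232, adjusted p = 0.0468) and PIM1 (0.57) on the higher side. On the lower side were CXCL9 (−1.60), ATM (−1.58), GBP5 (−1.42), IKZF1 (−1.34), KLC3 (−1.32), UBD (−1.31), CLUH (−1.27), REL (−1.25, though −1.15 and not called without that array), MAGOH (−1.24), SIAE (−1.20), FUT6 (−1.19), GBP1 (−1.13), RRS1 (−0.531) and MRTO4 (−0.531). Among lists, hypoxia (median 0.236) and cell cycle (0.112) were higher, and MYC and ribosome biogenesis (−0.214) and the mitochondrial ribosome (−0.0914) lower, of which the last 2 turned to 0.202 and 0.304 with median centring. With an estimated correlation none was called (adjusted p = 0.484, 0.254, 0.260 and 0.254).

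Inhibitor and JAK2 shRNA differed in 3766 genes at 24 and 48 h. Those given here are JAK2 and examples from the lists, not chosen as the largest differences. Higher with the inhibitor were EGR1 (2.50), CCL4 (1.56), TNF (1.11), NDUFB3 (0.995), NHP2 (0.813), RPS16 (0.803) and JAK2 (0.566). Lower were NFIL3 (−2.30), ADM (−2.23), HK2 (−2.15), BIRC5 (−2.14), BNIP3 (−2.05), PLK1 (−1.97), CISH (−1.68), JCHAIN (−1.64), CCNB2 (−1.63), CEBPB (−1.57), MAL (−1.55), SOCS3 (−1.15), PSAT1 (−1.03), PIM1 (−0.973) and MYC (−0.631). Lists that differed were JAK-STAT targets (median −0.271), STAT6 targets (−0.762), cell cycle (−0.713), hypoxia (−0.838), ATF4 stress response (−0.477) and plasma cell genes (−0.266) on the lower side. On the higher side were NF-kB targets (0.532), cytosolic ribosomal proteins (0.386), oxidative phosphorylation (0.353) and MYC and ribosome biogenesis (0.289), all of which turned below 0 with median centring (−0.009, −0.04, −0.12 and −0.20). With an estimated correlation none of these 10 lists was called (smallest adjusted p = 0.331).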

How the results depend on the processing

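Leaving out each inhibitor array, each array of the inhibitor minus JAK2 shRNA comparison and each array for the list tests was chosen after the data were seen. Of 5645 values of named genes under all alternatives, 5046 counted as the same, and of 3216 list values 2977 did. For a called gene or list this meant the same direction and still a call. An uncalled gene had to stay uncalled and within its SE of the main value. An uncalled list had only to stay uncalled, in either direction. The counts of all 6 gene comparisons stayed within 1.5 times of their value without the filter on dim probes, with the stricter filter and with the mean of a gene's probes. The means and the difference did so with 1 fit of all 16 arrays, the shRNA means with each arm alone, and the difference with time as a block. The signal over background limits what dim genes can show.

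With the scanner software's processed signals the counts were 3429 for the inhibitor (1953 higher, 1476 lower), 799 for its trend (408, 391), 8004 for the JAK2 shRNA (4733, 3271), 4849 for the JMJD2C shRNA (2759, 2090), 1850 for their difference (796, 1054) and 3821 called alike. With the deposited series values, made from the same signals, they were 3418, 797, 7987, 4822, 1840 and 3815. With median centring they were 23 (2 higher, 21 lower), 0, 10197 (9750, 447), 6622 (6443, 179), 3942 (3555, 387) and 6156 (6082, 74), and 6740 (871, 5869) for the inhibitor minus the JAK2 shRNA. Of the calls made with loess 2523 were still called in the JAK2 shRNA arm, 1416 in the JMJD2C shRNA arm, 524 in their difference and 2472 in the inhibitor minus the JAK2 shRNA. No background correction gave 955 trend genes (538, 417). The cause was not tested in these cases.

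With no size minimum the counts were 8783 for the inhibitor, 12193 and 11037 for the JAK2 and JMJD2C shRNAs, 2492 for their difference, 5962 for the inhibitor minus the JAK2 shRNA and 8390 alike. With a minimum of 1 they were 75 (13, 62), 711, 219, 114 (11, 103), 671 and 140, and 178 for the trend, as the limit itself sets. Array weights gave 831 trend genes (488, 343), 1285 for the difference of the shRNA arms and 618 for the shRNA trends (154, 464), where 21358 tests had an unadjusted p below 0.05, and the cause was not tested. The 16, 24 and 48 h arrays alone gave 2599 inhibitor genes and the rank of time 1608 trend genes (863, 745), and the cause was not tested. With slide as a fixed block the trend had 0. The share of this due to smaller sizes, a larger SE and fewer degrees of freedom was not tested. The slopes of the shRNA arms correlated at 0.5766 where their means did at 0.811. Camera with an estimated correlation called 9 lists in place of 73.

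Leaving out 1 array gave 3720 to 4491 genes for the JAK2 shRNA, 1835 to 3222 for the JMJD2C shRNA, 539 to 1097 for their difference (lowest without the 72 h JAK2 shRNA array), 1550 to 2249 alike, and 0 for the shRNA trends in each case by limma (1232 to 4241 at unadjusted p below 0.05). It gave 939 to 1478 for the inhibitor and 2599 to 4111 for the inhibitor minus the JAK2 shRNA. The inhibitor trend ran from 0 to 2451 genes: 2451 without the 0.5 h array, 87 without the 2 h, 118 without the 4 h, 185 without the 6 h, 118 without the 8 h, 677 without the 16 h, 0 without the 24 h and 0 without the 48 h array, and the cause was not tested. The arms' Pearson r was 0.783 to 0.822 and their Spearman rho 0.799 to 0.825.

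Directions turned with median centring, where the median of all genes shifted by 0.427 in the JAK2 shRNA arm and 0.249 in the JMJD2C shRNA arm. In the JAK2 shRNA arm JAK2 was 0.0684, MYC 0.152, HSPA5 0.0701 and CYCS 0.195, and KDM4C was 0.0458 in the JMJD2C shRNA arm. List medians were 0.486 (PMBL signature), 0.450 (NF-kB), 0.558 (ER chaperones), 0.911 (oxidative phosphorylation) and 0.585 (mitochondrial ribosome) in the JAK2 shRNA arm. In the JMJD2C shRNA arm they were 0.297 (PMBL signature), 0.371 (p53), 0.459 (cholesterol), 0.464 (oxidative phosphorylation) and 0.320 (mitochondrial ribosome). In the difference they were 0.202 (MYC) and 0.304 (mitochondrial ribosome), and MYC was −0.204 in the inhibitor minus the JAK2 shRNA. Of these lists oxidative phosphorylation alone was called in the opposite direction, in both shRNA arms (camera adjusted p = 0.00735 with the JAK2 shRNA and 0.0409 with the JMJD2C shRNA). Other called lists had medians that crossed 0 and lost their call while the test kept its direction. These were cell cycle (0.00), cholesterol (0.12) and heat shock (0.05) with the inhibitor, and NF-kB (−0.14) in its trend. They were MYC (0.15), interferon (0.31) and heat shock (0.18) with the JAK2 shRNA, and NF-kB (0.28) and ER chaperones (0.01) with the JMJD2C shRNA. In the inhibitor minus the JAK2 shRNA they were NF-kB (−0.01), oxidative phosphorylation (−0.12) and ribosomal proteins (−0.04). Arrays of 4 h and later minus the 0.5 h array turned H2AC19 (−0.0985), MYC (0.0585), SOCS3 (0.0703), VASP (0.147), JUN (0.313) and CD274 (0.317), since each stood farther from 0 on the 0.5 h array than on average later. Without the 24 h JMJD2C shRNA array the STAT6 list in that arm's trend was −0.0853, and 0.348 without the 96 h array, and the cause was not tested.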

Other observations

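Leaving out inhibitor arrays was chosen after the data were seen, and the other tests in this part were planned.

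Of genes that mark B cell identity, 6 were called with the JAK2 shRNA. BACH2, a repressor of plasma cell differentiation, rose by 1.22 and POU2AF1 by 0.85, with BCL6 (0.73), BLK (0.67) and CD79A (0.52, and 0.47 and not called without the 48 h array) also higher, CD40 (−0.67) lower and 12 of 18 not passed (camera adjusted p = 0.404). With the JMJD2C shRNA BACH2 (0.99) alone of that list was called and 17 of 18 did not pass (adjusted p = 0.482), and with the inhibitor 0 of 17 passed by limma (adjusted p = 0.985, median −0.00 where the mean was 0.04). Plasma cell genes had JCHAIN (0.83), CREB3L2 (0.75) and CD38 (0.66) higher, FKBP11 (−0.74), IRF4 (−0.72), MZB1 (−0.56) and SSR4 (−0.51, and −0.50 and −0.49 and not called without the 48 h or the 72 h array) lower and 7 of 14 not passed with the JAK2 shRNA (adjusted p = 0.908). With median centring CD40 (0.38), FKBP11 (0.38), IRF4 (0.20), MZB1 (0.58) and SSR4 (0.72) stood above 0 in that arm, and FKBP11 (0.12) in the JMJD2C shRNA arm. With the JMJD2C shRNA they had CD38 (0.55, and 0.44 and not called without the 72 h array) higher, MZB1 (−0.75), IRF4 and FKBP11 lower and 10 of 14 not passed (adjusted p = 0.444). MHC class II genes, which present antigen, had HLA-DOA higher in both shRNA arms (0.72 and 0.50, with further probes at −0.04 to 0.02 and at −0.08 to 0.08, the latter call 0.39 and not called without the 72 h array), 12 of 13 not passed in each (adjusted p = 0.183 and 0.301) and 0 of 13 passed with the inhibitor (adjusted p = 0.315).

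Among genes of the BCL2 family, which set the threshold for apoptosis, BCL2L11 was higher with the inhibitor (0.71), the JAK2 shRNA (0.83) and the JMJD2C shRNA (0.59, and 0.50 and not called without the 72 h array), though 1, 1 and 2 of its 4 further probes went the other way. BCL2L1 fell with both shRNAs (−0.82 and −0.77), and BAX (−0.61) fell with the JAK2 shRNA, BBC3 (−1.22) and HRK (−1.12) with the JMJD2C shRNA and BBC3 (−0.55) with the inhibitor. Without the 72 h array BBC3 (−0.62) and HRK (−0.68) were not called with the JMJD2C shRNA, nor without the 96 h array (−1.20 and −1.08), and BBC3 (−0.43) was not called with the inhibitor without the 48 h array. Of 15 genes 13, 12 and 11 did not pass in the inhibitor, JAK2 shRNA and JMJD2C shRNA arms (adjusted p = 0.504, 0.817 and 0.136). The p53 targets had BBC3 and PHLDA3 (−0.60) lower with the inhibitor and 17 of 19 not passed (adjusted p = 0.321). With the JAK2 shRNA they had TP53INP1 (0.57) higher, ZMAT3 (−0.68), MDM2 (−0.65, with a second probe at 0.09, and −0.56 and not called without the 96 h array), BAX, CDKN1A (−0.52) and PHLDA3 (−0.50) lower and 12 of 18 not passed (adjusted p = 0.108). Calls lost there without 1 array were those of TP53INP1 (0.46, 24 h), PHLDA3 (−0.45, 48 h, and −0.48, 72 h) and CDKN1A (−0.49, 72 h), and with median centring BAX (0.32), CDKN1A (0.48) and PHLDA3 (0.36) stood above 0. H3K9 and heterochromatin genes had KDM3A (0.84), EHMT1 (0.79), UHRF1 (0.77) and KDM1A (0.55) higher, SUV39H2 (−0.70) and TRIM28 (−0.61) lower and 13 of 19 not passed with the JAK2 shRNA (adjusted p = 0.453, with SUV39H2 at 0.13 and TRIM28 at 0.41 with median centring), and 0 of 19 passed with the inhibitor (adjusted p = 0.504). Immediate early genes had EGR1 (0.99) higher, MYC, EGR2 (−0.79), JUN (−0.78) and DUSP6 (−0.66) lower and 11 of 16 not passed with the inhibitor (adjusted p = 0.170). JUN stood at 0.31 on the arrays from 4 h on relative to the 0.5 h array, so a change by 0.5 h and a dye bias cannot be told apart. EGR1 was not called without the 4, 6, 8, 16, 24 or 48 h array (0.64 to 1.07) and EGR2 not without the 0.5, 4, 6 or 8 h array (−0.71 to −0.77). They had 2 higher and 4 lower of 18 with the JAK2 shRNA (adjusted p = 0.406) and 0 higher and 3 lower with the JMJD2C shRNA (adjusted p = 0.206). In the 9p24 segment CD274 and SLC1A1 (−0.52) fell with the inhibitor and 22 of 24 did not pass (adjusted p = 0.315). CD274 (−0.49) was not called without the 2 h array and SLC1A1 (−0.46 to −0.50) not without the 4, 6, 24 or 48 h array.

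JAK-STAT targets with the JMJD2C shRNA had PIM1 (0.69) and IL2RA (0.54, with a second probe at 0.01, and 0.42 and 0.49 and not called without the 72 h or the 96 h array) higher, MYC and BCL2L1 lower and 13 of 17 not passed (adjusted p = 0.301), and STAT6 targets had 1 higher, 4 lower and 10 of 15 not passed (adjusted p = 0.186). ER chaperones (adjusted p = 0.060) and oxidative phosphorylation genes (adjusted p = 0.660, with UQCRH at 0.53 called) did not pass as lists with the inhibitor, nor did NF-kB targets (adjusted p = 0.390), of which NFKBIA (0.55) was higher and CD83 (−0.62) and REL (−0.56) were lower. UQCRH was not called without the 16, 24 or 48 h array (0.46, 0.46 and 0.48), nor NFKBIA without the 16 or 48 h array (0.50 and 0.48). Cholesterol synthesis genes (adjusted p = 0.523, with STARD4 at 0.59 called) and histones (adjusted p = 0.523, with H1-2 at 0.55 called) did not pass with the JAK2 shRNA. T cell markers had 0 called in any of the 3 means (adjusted p = 0.985, 0.902 and 0.758). Monocyte and granulocyte markers had 0 called with the inhibitor and the JAK2 shRNA and ITGAM (0.51, and 0.46 and 0.50 and not called without the 72 h or the 96 h array) with the JMJD2C shRNA (adjusted p = 0.321, 0.745 and 0.977). Smaller drifts over time within the shRNA arms were those of STAT6 targets (median 0.17, adjusted p = 0.0102), PMBL signature (0.17, adjusted p = 0.0386) and cholesterol synthesis genes (0.08, adjusted p = 0.0102) with the JAK2 shRNA, all at adjusted p = 0.757 with an estimated correlation. With the JMJD2C shRNA they were those of STAT6 targets (0.14, adjusted p = 0.0244), 9p24 genes (0.09, adjusted p = 0.0461) and ER chaperones (−0.18, adjusted p = 0.0412), at adjusted p = 0.734 with an estimated correlation, and immediate early genes (0.07, adjusted p = 0.0363, adjusted p = 0.640 with an estimated correlation). Without the 24 h JMJD2C shRNA array, left out after the data were seen, the STAT6 list turned to −0.0853 and was not called.

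The spread of the control channel between arrays (median SD of log2 intensity) was 0.108 in the inhibitor arm, 0.119 in the JAK2 shRNA arm and 0.0503 in the JMJD2C shRNA arm for Cy3, and 0.158, 0.149 and 0.131 for the treated Cy5 channel.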
